A study of Oncorhynchus kisutch with 82 samples.

How the data were processed

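Gill RNA of juvenile coho salmon (Oncorhynchus kisutch) was measured on 82 arrays, with a separate fish on each array. Per the labels' protocols, tissue was homogenised in TRI reagent, and RNA was extracted with MagMAX-96 kits and amplified with Amino Allyl MessageAmp kits. The amplified RNA of each fish and a pool of gill RNA carried different Alexa dyes, the same way round on every array, per the labels. The arrays lie on 31 slides, which also held arrays of sockeye salmon that were not analysed here.

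The authors deposited a log ratio of the 2 channels for each spot. The deposited log ratios were already centred, with array medians between -0.151 and 0.167. Scanner, background correction, normalization and the rule that left values empty are not given in the sources used here. Neither the log base nor the direction of the ratio is stated per the labels or the file headers. The values were taken as log2, because on a natural log scale the lowest value, -11.30, would be a ratio of 80993, beyond the range usual for scanners. Whether a higher log ratio means more or less RNA in the fish than in the pool stays open, so differences below are differences of the deposited log ratio. Sizes in fold hold only if the values are log2.

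The table used held 43236 probes and 60 control spots, which were left out. Of the possible probe values 45.6% were empty. A value was present on every array for 7379 probes, and 2668 probes had none on any array. The authors' series table of the same arrays held identical values wherever both had one, likewise taken as log2, but lacked 17574 values of 1 array. It was used as an alternative. No empty value was filled in. The number of arrays limits the precision of each comparison.

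Groups were taken from the season given in the labels, and year, origin, sex, capture area and slide from the labels too. For 1 fish, the slide in its array position differed from that in its raw data name, and the slide of the array position was used. The most alike arrays had r = 0.951 over their shared probes and no array repeated another. No pair of arrays had r below -0.3, and the lowest r was -0.250.

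Each comparison was fitted per probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and p-values were adjusted by Benjamini-Hochberg within the comparison. A probe was called at an adjusted p below 0.05. A probe entered a comparison when at least 50% of the fish, and at least 2, had a value in each group. The 5 stage comparisons used all 82 arrays with year and origin as covariates. Origin, year and sex at sea were tested in ocean summer and fall fish, with stage among the covariates. Origin in fresh water was tested in the river smolts of 2008, and 3 interaction terms tested whether a stage difference depended on year or origin. All these designs were fixed before the data were examined.

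The files pair no probe with a gene, and the gene table at hand lists no probes. Gene lists fixed beforehand could therefore not be tested, and probes could not be averaged per gene. The rule for naming probes was, per comparison, the 2 largest increases and 2 largest decreases among called probes. For smolt to summer and summer to fall, the same direction was also required in each year fitted alone.

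The fits were tested on simulated log ratios with the real missing values, the residual spread of each probe, the spread of each array and 200 changed probes. Noise was drawn independently for each probe and array, so variation shared across probes was left out. The false calls therefore do not measure the error in the real arrays. In the smolt to summer design, run on 22149 probes, 72.3% of changes of 1 log2 unit and 98.4% of changes of 2 log2 units were recovered, with 4 false calls among 185. In the smolt to spring design, run on 22654 probes, these shares were 23.0% and 86.8%. In the fall to winter design, run on 18705 probes, they were 12.3% and 69.1%.

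Alternatives covered centring, quantile normalization, the series table, probes without missing values, slide as a random or fixed block, array position, the variance prior (with a trend over the mean log ratio, since intensities were not used here), covariates and subsets of fish. After the data were seen, arrays with a wide spread of log ratios were left out as a further alternative. These were the 14 arrays whose SD exceeded the median SD by over 3 scaled median absolute deviations, which put the limit at 1.30. Array weights, all probes with an estimable difference, and slide blocks or capture area in further comparisons were also added then. Plots were drawn with matplotlib.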

Results

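The deposited data cover gill of coho salmon caught as smolts in rivers and as postsmolts at sea, in 2008 and 2009. There were 27 river smolts, 4 fish of the ocean spring, 22 of the ocean summer, 27 of the ocean fall and 2 of the ocean winter. Fork length averaged 11.3 ± 1.97 cm (SD, n = 27) in smolts, 17.5 ± 2.19 cm (SD, n = 22) in summer fish and 25.5 ± 2.21 cm (SD, n = 27) in fall fish. The spring fish were all wild and of 2009, and the winter fish were both hatchery fish of 2009. An array gave a value for 12606 to 31972 probes, with a median of 23735. The SD of the log ratios on an array ranged from 0.636 to 1.88 around a median of 0.861. On 14 arrays it lay above 1.30. These were 7 smolts of 2008, 5 summer fish of 2009 and 1 fall fish of each year. Probes are named by their array IDs, and "higher" refers to the deposited log ratio, whose direction is not settled.

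**Figure D1:**
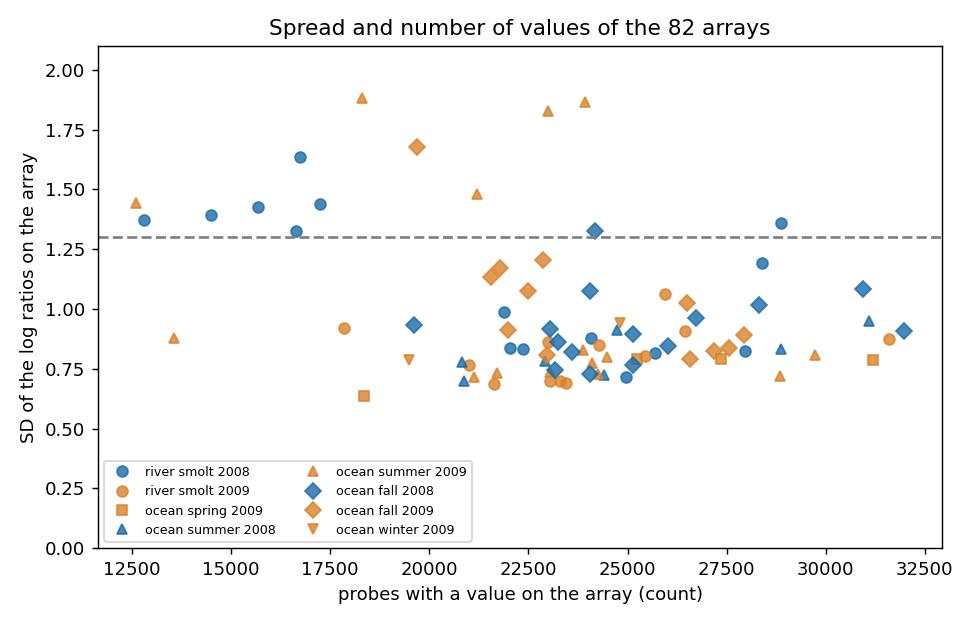
Number of probes with a value (x axis) against the SD of the log ratios (y axis) for each of the 82 arrays, with symbols for stage and colours for year. The dashed line marks an SD of 1.30, above which 14 arrays lie.

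The series asks how gill transcription shifts as juvenile coho move from fresh water into the sea. Between river smolts and ocean summer fish, probe C071R121 had a log ratio of 0.47 ± 1.35 (SD, n = 27) in smolts and -4.09 ± 1.35 (SD, n = 21) in summer fish. C259R057 went from 2.43 ± 1.36 (SD, n = 27) to -2.08 ± 1.19 (SD, n = 14). In the other direction, C153R120 went from -3.21 ± 1.21 (SD, n = 27) to -0.05 ± 0.77 (SD, n = 22), and C168R092 from -3.35 ± 1.30 (SD, n = 27) to -0.90 ± 2.27 (SD, n = 22). Adjusted p in limma was 6.48e-17, 7.2e-13, 8.7e-14 and 1.11e-05 in that order. The 5 wide-spread summer arrays held the 5 lowest summer values of C168R092, from -5.09 to -3.81, and the others ranged from -2.72 to 1.14. Without the wide-spread arrays its difference was 3.95 against 2.80. Of 22149 probes tested, 3905 were called, 1695 higher and 2210 lower in summer fish. The difference was at least 2-fold for 631 of them. With the wide-spread arrays left out, a choice made after seeing the data, 6044 probes were called, 3091 of them among the 3905.

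**Figure D2:**
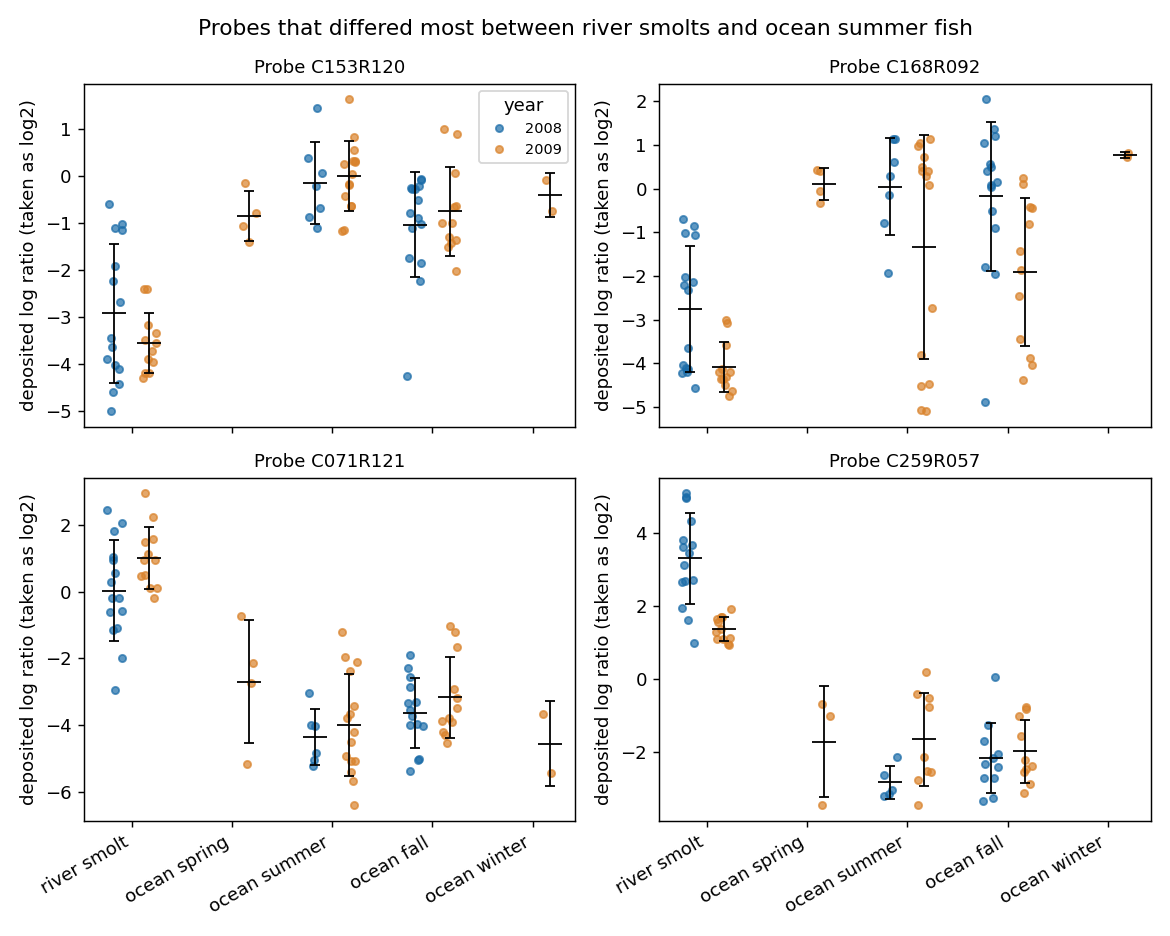
Deposited log ratio, taken as log2 (y axis), of the 4 probes named for smolt to summer, by stage (x axis) and year (colour); points are fish, and bars are the mean and SD of a stage and year. C071R121 averaged 0.47 in river smolts and -4.09 in ocean summer fish.

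With all arrays the size of this difference depended on the year, but without the wide-spread arrays it did so for few probes. In this comparison those arrays were smolts of 2008 and summer fish of 2009 only. The interaction of stage and year was called for 5804 of 20403 probes in limma. Fitted alone, 2008 gave 6811 calls and 2009 gave 1162. Of 6679 probes called in 2008 and fitted in both years, 2518 (37.7%) had the same sign in 2009. Across 20403 probes, which are not independent replicates, the summer-minus-smolt differences of the separate years had r = -0.140 and rho = -0.158. Without the wide-spread arrays, r was 0.605 and rho 0.595 over 22293 probes, and the interaction was called for 48 probes. Smolts of 2008 came from the Chilliwack, and those of 2009 from other rivers, so year and river cannot be told apart in smolts. The labels give the smolts of 2008 the stock region Chilliwack, which no summer fish has. Stage and stock therefore cannot be told apart in the fish of 2008, which also enter the fit of both years.

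**Figure D3:**
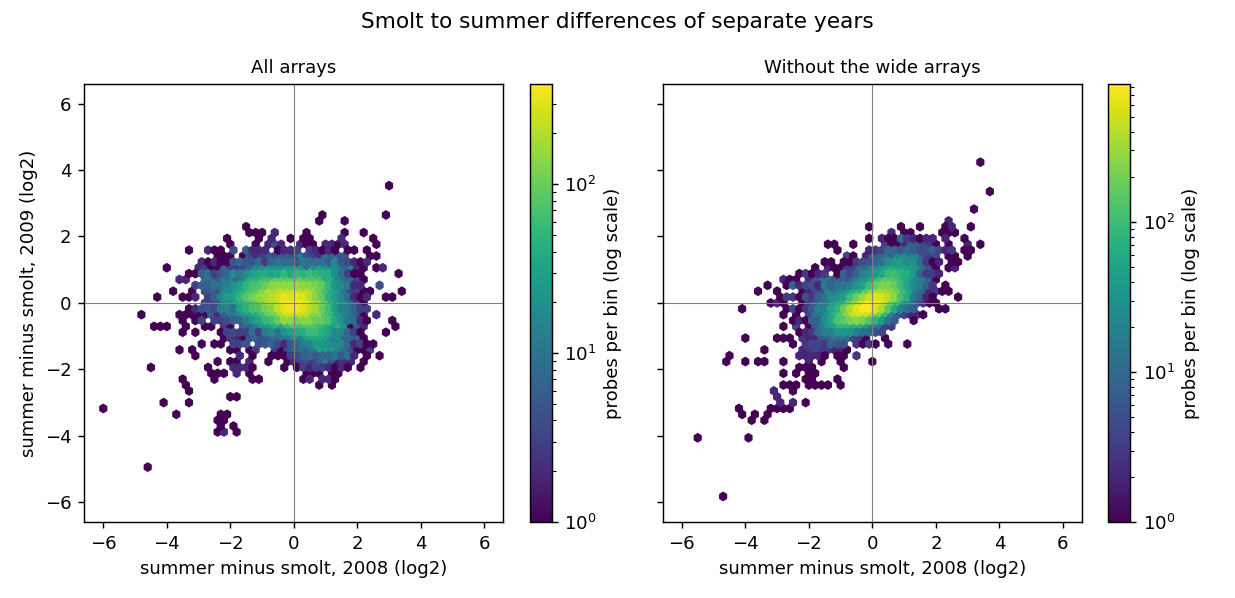
Difference of ocean summer fish minus river smolts (log2) in 2008 (x axis) against 2009 (y axis), with colour for the number of probes per bin on a log scale. The left panel uses all arrays (r = -0.140), and the right panel leaves out the wide-spread arrays (r = 0.605).

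Spring fish were compared with smolts to describe early sea residence. C140R014 was higher in spring fish, at 1.53 ± 0.63 (SD, n = 4) against -1.85 ± 1.51 (SD, n = 27). C168R092 was also higher, at 0.11 ± 0.36 (SD, n = 4) against -3.35 ± 1.30 (SD, n = 27). C220R169 was lower, with -2.26 ± 0.15 (SD, n = 2) against 1.52 ± 1.06 (SD, n = 21), and so was C231R155, with -2.37 ± 1.52 (SD, n = 2) against 1.62 ± 1.16 (SD, n = 25). Adjusted p in limma was 0.0187, 0.00748, 0.00558 and 0.0142 in that order. In wild fish of 2009 alone, where year and origin do not vary, none of the 4 was called (adjusted p in limma from 0.0521 to 0.102), with differences of 4.79, 3.55, -4.30 and -4.24. C140R014 also lost its call without spring fish 2134, 2247 or 2248, with differences from 4.11 to 4.47, and with stage as the only term, with 3.37. C220R169 and C231R155 had values in spring fish 2134 and 2248 only, so they could not be tested without either. In all, 1491 of 22654 probes were called, 880 higher and 611 lower in spring fish, and 1255 differed at least 2-fold. Among probes with a value on every array the balance turned, to 106 higher and 231 lower. Leaving out single spring fish cut the count to 502 (fish 2133), 57 (fish 2134), 86 (fish 2247) and 281 (fish 2248). Without fish 2133, 262 were higher and 240 lower, but the balance turned without the others, to 24 and 33, 33 and 53, and 124 and 157. It also turned with array weights (3882 higher and 4509 lower) and was even with array position as a covariate (354 and 355). In wild fish of 2009 alone 622 were higher and 220 lower. With stage as the only term, 863 probes were called, 240 higher and 623 lower. Quantile normalization raised the count to 5104 (2591 higher and 2513 lower), and leaving out the wide-spread arrays raised it to 2905 (1488 higher and 1417 lower).

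Between spring and summer fish, limma called 0 of 23269 probes, with 3005 at an unadjusted p below 0.05. Without the wide-spread arrays it also called 0, with 1290 of 23783 at an unadjusted p below 0.05. The simulation of this design recovered 19.7% of changes of 1 log2 unit and 84.1% of changes of 2 log2 units. Smaller differences could therefore be missed. Quantile normalization gave 10 calls and array weights 212.

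From summer to fall, C101R031 was lower in fall fish, at -5.19 ± 1.77 (SD, n = 27) against -1.45 ± 2.47 (SD, n = 22), and C192R014 was lower at -4.80 ± 1.87 (SD, n = 27) against -1.15 ± 2.78 (SD, n = 22). C010R109 was higher, at 0.69 ± 1.71 (SD, n = 27) against -0.86 ± 2.13 (SD, n = 22), as was C061R085, at 1.26 ± 1.40 (SD, n = 27) against -0.19 ± 1.91 (SD, n = 22). Adjusted p in limma was 1.36e-06, 3.07e-05, 0.000375 and 0.0232 in that order. In all, 509 of 23141 probes were called, 232 higher and 277 lower, and 188 of the 215 probes with at least a 2-fold difference were lower in fall fish. The balance turned among probes with a value on every array (123 higher and 98 lower), with quantile normalization (318 and 268) and with array weights (664 and 544). It stayed with centring (220 and 288) and without the wide-spread arrays (265 and 288). Within slides, with slide as a fixed block, 4 probes were called. None of the 4 named probes was among them, with differences of -3.15 for C101R031, -2.42 for C192R014, 1.93 for C010R109 and 0.96 for C061R085. Within slides the median difference of the 509 probes fell from 0.90 to 0.64 on the log2 scale, while its median SE rose from 0.22 to 0.30. C061R085 also lost its call without the wide-spread arrays, with a difference of 1.21, and with sex as a covariate, with 1.40. With stage as the only term C010R109 and C061R085 were not called, with differences of 1.55 and 1.45. Single slides held too few fish for values within each. In 2008 alone 7 probes were called, none of them a named one, and in 2009 alone 319, without C010R109 and C061R085. The differences in 2008 and 2009 were 3.35 and 1.24 for C010R109, against 2.13 in both years together, and 1.65 and 1.31 for C061R085, against 1.61. For C101R031 they were -3.21 and -4.47, against -4.10, and for C192R014 -2.32 and -4.55, against -3.87. With all arrays, neither interaction was called for any probe. For year, 611 of 21960 probes had an unadjusted p below 0.05 in limma, and for origin 204 of 21473. Without the wide-spread arrays the year interaction had 5 calls, with 2247 of 22500 probes at an unadjusted p below 0.05. Across probes, which are not independent, the summer to fall differences of the separate years had r = 0.386 and rho = 0.253. Without the wide-spread arrays these were 0.182 and 0.0278. The simulation of the year interaction recovered 14 of 61 changes of 1 log2 unit. The lack of calls therefore does not show that the years were alike.

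Between fall and the 2 winter fish, 8 of 18705 probes were called in limma. C098R092 was higher in winter fish, at 2.97 ± 0.08 (SD, n = 2) against -0.42 ± 1.14 (SD, n = 27), with an adjusted p of 0.00345 in limma. Its call was lost without either winter fish, with differences of 3.58 and 3.46. C136R168 was higher at 4.12 ± 5.53 (SD, n = 2) against 0.36 ± 0.40 (SD, n = 26), and its difference of 3.79 turned to -0.12 without winter fish 4215. With quantile normalization of all arrays it was 2.14. C093R121 was lower, at -2.57 ± 3.81 (SD, n = 2) against 0.46 ± 0.66 (SD, n = 27), and C082R010 at -2.22 ± 1.81 (SD, n = 2) against 0.31 ± 0.79 (SD, n = 24). Without winter fish 4207 their differences went from -3.15 to -0.46 and from -2.54 to -1.26. Without winter fish 4215 both were larger in size than with the 2 fish together, so they rest mainly on fish 4207. In hatchery fish of 2009 alone, where year and origin do not vary, C136R168, C093R121 and C082R010 lost their calls, with differences of 3.80, -3.35 and -2.83. Array weights gave 1823 calls. The winter fish were of another stock than all fall fish with a recorded stock, so stage and stock cannot be told apart. Fall fish 796 has no recorded stock. Only 1 fall fish came from the capture area of the winter fish. No slide held both fall and winter fish, so no comparison within slides exists.

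Hatchery and wild fish were compared in the river smolts of 2008, all from the Chilliwack. C019R156 was the only probe called among 18469, at -3.21 ± 0.76 (SD, n = 8) in hatchery and 0.24 ± 1.34 (SD, n = 7) in wild smolts, with an adjusted p of 0.0263 in limma. Array weights gave 3421 calls in these smolts, quantile normalization 43, and the probes with a value on every array 13. Fish 36 was a hatchery smolt of 5 cm. The other hatchery smolts measured 12.5 to 14.1 cm and the wild smolts 9.1 to 12.1 cm, so without fish 36 size and origin cannot be told apart. Wide-spread arrays were 5 of the 8 hatchery and 2 of the 7 wild smolts. Without fish 36, 205 probes were called, and none with fork length as a further covariate. The difference of C019R156 was then -3.62, and with array position as a covariate, which also ended its call, it was -3.44, against -3.45 without these terms. Its call was lost without the wide-spread arrays too, with a difference of -3.80. In ocean fish, limma called 0 of 23214 probes for origin, with 172 at an unadjusted p below 0.05. That is 0.741% of them, fewer than tests without any difference would give on average. Without the wide-spread arrays the count was 443 of 23429, and with array weights 1069 of 23214. The cause of the low count was not tested, so it does not measure how alike the origins were. For sex in ocean fish, limma called 0 of 23377 probes, with 1286 at an unadjusted p below 0.05. In ocean fish array weights gave 0 calls for origin and 44 for sex.

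Between the years, in ocean fish, C010R109 was higher in 2009, at 0.88 ± 1.08 (SD, n = 27) against -1.10 ± 2.42 (SD, n = 22), and C131R170 at 1.62 ± 0.96 (SD, n = 27) against -0.35 ± 2.15 (SD, n = 20). C139R012 was lower, at -1.89 ± 2.62 (SD, n = 27) against 0.57 ± 1.74 (SD, n = 22), as was C083R035, at -2.26 ± 3.05 (SD, n = 27) against 0.17 ± 1.88 (SD, n = 22). In limma, 3459 of 22832 probes were called, 1956 higher and 1503 lower in 2009. Of these, 708 differed at least 2-fold, with the opposite balance of 197 higher and 511 lower. Summer fish alone gave 5 calls and fall fish alone 0. In summer and in fall fish the differences were 3.91 and 1.44 for C010R109, against 2.47 in the full fit, and 3.83 and 1.24 for C131R170, against 2.29. C139R012, with -2.63 and -2.50 against -2.56, and C083R035, with -2.76 and -2.27 against -2.48, were called in neither stage alone. Array position as a covariate left 46 calls, leaving out the wide-spread arrays left 642, with the balance turned to 280 higher and 362 lower, and slide as a fixed block left 0. Within slides the differences were 1.81 for C010R109, 1.84 for C131R170, -1.26 for C139R012 and -0.91 for C083R035. C139R012 and C083R035 lost their calls with array position, with differences of -2.33 and -2.26, and C083R035 also without the wide-spread arrays, with a difference of -1.74, and with array weights, with -1.22.

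**Figure D4:**
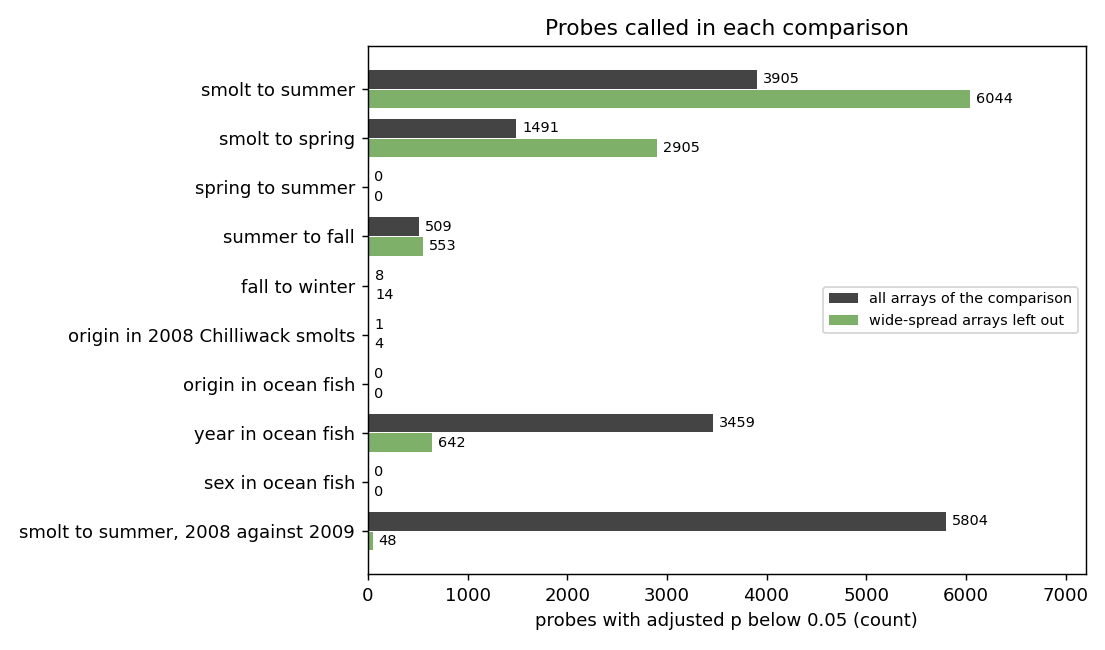
Number of probes with an adjusted p below 0.05 (x axis) in each comparison (y axis), with all arrays of that comparison (dark bars) and with those of them that have a wide spread left out (green bars). The interaction of stage and year, fitted on 49 arrays, went from 5804 to 48 probes.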

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

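The tests of wide-spread arrays and of local defects were chosen after their results had been seen. The slide blocks for these patterns and capture area were chosen after the data had been seen, though before their own results. The demand that a cause also shrink the differences was added once the counts were known. Among 6 groups of 4 to 10 fish tested, 1 held a fish far from the others, where chance marks about 1 in 20. Spring fish 2133 had an array SD of 0.636, against 0.785 for the next lowest of the 4 spring arrays. The year difference of C259R057 from smolt to summer was 3.16 on the log2 scale, 2009 minus 2008, by the interaction test. Outside the probes compared, control spots had values. DarkCorner and GE_BrightCorner had one on 82 of 82 arrays, E1A_r60_3 on 79, 3xSLv1 on 57, E1A_r60_a22 on 55, ETG10_195139 on 47 and E1A_r60_a20 on 43. Their log ratios averaged -0.0882 ± 0.899 (SD over 82 arrays) for DarkCorner and 0.407 ± 0.378 (SD over 79 arrays) for E1A_r60_3.

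The stage difference from smolt to summer differed between years at 5804 probes, against at most 4281 in the other 99 of 100 splits of the fish. Only the real grouping reached its count (1 of 100, the smallest share these splits can give). The split with 4281 calls shows that other groupings of these fish can also give many calls, so chance is unlikely but not excluded. Leaving out the wide-spread arrays of this comparison, 7 smolts of 2008 and 5 summer fish of 2009, left 48 calls. Fewer fish alone did not account for that, since 0 of 100 random removals of as many fish per stage and year gave so few, and the lowest gave 125. The median difference of 5781 of the 5804 probes went from 1.49 to 0.56, with 99.6% keeping their sign. These probes were chosen by the fit with all arrays and refitted on a part of the same arrays, so the kept sign is largely built in. A smaller year or river difference stays open, untested. With slide as a fixed block 1398 probes were called and the median was 1.31 against 1.49, which leaves the part of the slides open.

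The year difference in ocean fish, 3459 probes, was larger than in the other splits (1 of 100), but the highest of them gave 3105. That split points to a structure of the samples that can give nearly as many, so chance is unlikely but not excluded. Capture area as a covariate gave 10566 calls. That term was the same in both years and could not take up an area difference confined to a single year. It therefore does not decide the part of capture area. Without the wide-spread arrays 642 probes were called and the median difference went from 0.71 to 0.51, so those arrays may account for part of it. Slide as a fixed block gave 0 calls, with the median at 0.45 and its SE up from 0.22 to 0.34. Of 25 slides with summer or fall fish only 8 hold both years, so slide and year stay hard to separate, and a biological difference of the years remains open.

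The wide-spread arrays lie on 13 slides and correlate with each other at r between 0.210 and 0.951. The first principal component of the arrays held 46.3% of the variance and followed the array SD. Arrays of a slide were no closer on it than chance within stage and year (permutation p = 0.274). This gives no sign of slides there, but a slide effect that runs along with stage or year was taken out beforehand. Slides therefore stay open. Neighbouring spots hardly correlated on the 14 arrays with the most extreme scores, 12 of them wide-spread (median r = 0.0333), which argues against local defects as the cause for this set. The 2 highest of the 82 arrays were wide-spread smolts, fish 5 (r = 0.254) and fish 93 (r = 0.172), so a local defect stays open on these. Within stage and year, arrays with fewer values had higher scores (r = -0.406, permutation p = 0.00018). By rank, rho was -0.507 (permutation p = 1e-05, the smallest the resamples can give). Without the 2 arrays farthest from the median r was -0.372. In smolts of 2008, wide-spread fish 3, 4, 5, 7, 8 and 93 had 12805 to 17249 values, and wide-spread fish 100 had 28877. The smolts of 2008 that were not wide-spread had 21880 to 28380. In summer fish of 2009 the ranges overlapped, with 12606 to 23922 on wide-spread arrays and 13561 to 29720 on the others. Few values thus went with a wide spread in most of these smolts, but low signal as the cause of the wide-spread arrays stays undecided. Of the recorded labels, capture area went with some of these arrays. All 5 wide-spread summer fish of 2009 came from the area mid_SoG, as did summer fish 2786 and 2905 of that year, which were not wide-spread. The wide-spread fall fish came from other areas. Among smolts of 2008, 5 of 8 hatchery and 2 of 7 wild fish were wide-spread. Capture area was not tested as a cause of the spread. It stays open, as do RNA quality and a state of the fish that the labels do not record, and no biological explanation was tested.

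For the other results, the real smolt to summer count of 3905 stood against at most 2 in other splits (1 of 100). Smolt to spring, 1491, stood against at most 753 (1 of 100). By these counts chance is an unlikely source of both, though leaving out single spring fish left 57 to 502 calls for smolt to spring. Summer to fall, 509, was reached by 2 of 100 splits, the highest other giving 5081, and origin in smolts, 1, by 4 of 100, the highest other giving 2374. By this count chance is an unlikely source of the 509, but the split with 5081 calls points to a structure of the samples that can give as many, and 4 calls were left with slide as a fixed block. For origin in smolts any split with a call matches the real one, so the count says little about that probe. Where no probe was called, all 100 splits are as large by construction, so the splits decide nothing there. The highest others were 9042 for spring to summer, 0 for origin at sea, 1 for sex, and 9916 and 4640 for the summer to fall interactions with year and origin.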

How the results depend on the processing

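Wide-spread arrays, array weights, the dropped minimum of values and, outside smolt to summer and summer to fall, slide as a fixed block were chosen after seeing the data, as were capture area and the interactions' alternatives. Centring moved no count by over 1.5 times. Apart from the tests given above, the cause of the changes below was not tested. Fewer fish or probes entered the subsets, which alone did not account for the fall of the smolt to summer interaction without the wide-spread arrays. Quantile normalization gave 5104 calls for smolt to spring, 10 for spring to summer, 15 for fall to winter, 43 for origin in smolts, 3525 for the smolt to summer interaction and 3 for the summer to fall interaction with year. Probes with a value on every array gave 1600 calls for smolt to summer (27.4% higher against 43.4%), 337 for smolt to spring (106 higher and 231 lower), 221 for summer to fall (55.7% against 45.6%), 1 for fall to winter, 13 for origin in smolts, 1591 for year and 3543 for the smolt to summer interaction. Array position as a covariate gave 709 for smolt to spring, 0 for origin in smolts, 46 for year and 1 for the summer to fall interaction with year. Slide as a fixed block gave 3800 for smolt to spring, 4 for summer to fall, 2315 for fall to winter (by way of other stages, since no slide holds both), 0 for year, 1398 for the smolt to summer interaction and 14 for the summer to fall interaction with year. Without the wide-spread arrays there were 6044 for smolt to summer, 2905 for smolt to spring, 14 for fall to winter, 4 for origin in smolts, 642 for year (43.6% higher against 56.5%), 48 for the smolt to summer interaction and 5 for the summer to fall interaction with year. Array weights gave 9072 for smolt to summer, 8391 for smolt to spring, 212 for spring to summer, 1208 for summer to fall, 1823 for fall to winter, 3421 for origin in smolts, 44 for sex, 3781 for the smolt to summer interaction and 12 for the summer to fall interaction with year. Without a minimum of values there were 0 calls for origin in smolts, 1 for origin at sea, 977 for year, 2 for the summer to fall interaction with year and 1 for that with origin. Stage alone gave 863 for smolt to spring and 5 for fall to winter. For smolt to summer, 2008 alone gave 6811 and 2009 alone 1162; for summer to fall these were 7 and 319. Wild fish of 2009 gave 842 for smolt to spring, and hatchery fish of 2009 gave 4 for fall to winter. The series table gave 3 and the trended robust prior 18 for origin in smolts, which had 205 without fish 36 and 0 with fork length added. Capture area gave 10566 for year, summer fish alone 5 and fall fish alone 0. Leaving out each spring fish gave 57 to 502 calls for smolt to spring and 0 to 1 for spring to summer. Leaving out each winter fish gave 2 to 10 for fall to winter, with the lone fish assumed to vary like the other groups, and moved the difference of C136R168 from 3.79 to -0.12 and 7.70. The other 103 counts stayed within 1.5 times, and 268 of the values of named probes kept their direction and call, while 49 kept only their direction. Averaging probes per gene and the set tests were not run, for want of gene names, and the slide blocks could not be fitted for origin in smolts. No paired analysis was possible because each fish number occurs once. Signal over background was not available here.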

Other observations

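The tests of effects shared between years and of the ratio's direction were chosen after the result was seen; those of the spring and fall scores and of fork length were set before. Smolt to summer differences in 2008 and smolt to spring differences in 2009 come from separate fish and rivers. Across 20828 probes, which are not independent, they had r = 0.567 and rho = 0.598, and 5772 of 6771 probes called in 2008 (85.2%) had the same sign in spring fish. Both lists shared 195 probes, all of the same sign, against 171 for independent lists. Without the wide-spread arrays r was 0.571. For smolt to summer in both years, r without those arrays was 0.605, and 898 of 899 probes called in both had the same sign, against an overlap of 313 for independent lists. A shift on sea entry shared by years and rivers is a hypothesis consistent with these values. The exclusion is not neutral, since with all arrays r was -0.140. Smolt to summer differences of 2008 and summer to fall differences of 2009 had r = -0.315 without those arrays. There 24.7% of the probes called in 2008 kept their sign. With all arrays this r was 0.152 and the share 61.9%. Whether these correlations go beyond the first principal component was not tested.

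Probes called between smolt and summer fish of 2008 without the wide-spread arrays, 3742 in all, were scored in the fish of 2009. From each log ratio the probe's mean over all fish of 2009, wide-spread ones included, was subtracted. The score was the mean of these values, each given the sign of the 2008 difference. Its zero point therefore depends on the fish pooled, and only differences between groups can be read. Since those smolts and summer fish also differed in stock region, the score may hold stock as well as stage. The score was -0.119 ± 0.163 (SD, n = 12) in smolts, 0.410 ± 0.0828 (SD, n = 4) in spring fish, 0.305 ± 0.187 (SD, n = 10) in summer fish, 0.0972 ± 0.301 (SD, n = 11) in fall fish and 0.430 ± 0.0706 (SD, n = 2) in winter fish. Spring fish exceeded smolts by 0.529 (exact permutation p = 0.000549, adjusted over 8 tests 0.0022, two-sided), so spring fish may already carry the summer profile. Scores tended to be lower on arrays higher on the first principal component, which followed array SD. Fall fish 2623, at 57.8 on it, scored -0.363, and winter fish 4215, at -46.8, scored 0.480. At nearby positions scores still differed, with 0.483 for spring fish 2134 (-39.2) and 0.164 for smolt 1615 (-41.2). Whether the stage differences go beyond this component was not tested. The fall mean lay slightly nearer summer than smolts, by less than its standard error, a criterion added after the value was seen, which leaves its side open. With the signature and the scores taken over all arrays, spring fish exceeded smolts by 0.429 (exact permutation p = 0.0011, adjusted 0.00293), while summer fish were at -0.170 ± 0.715 (SD, n = 15). The arrays left out thus include the summer fish with the lowest scores, and the summer mean depends on leaving them out.

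If the ratio is sample over a pool of all fish, the mean log ratio of a probe should fall as its variance between fish rises. It did, from 0.00 in the 1778 least variable probes to -0.48 in the 1778 most variable ones, with rho = -0.129 across probes. This is a hint that the deposited ratio may be sample over reference, and it leaves the direction unsettled, since noise in dim spots was not excluded.

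Fork length within stage and year was called for 0 of 20484 probes in limma over 79 fish, with 5608 at an unadjusted p below 0.05, and 0 of 21751 without the wide-spread arrays, with 723 at an unadjusted p below 0.05. Whether a probe had a value differed between smolts and summer fish for 12 of 31264 probes (Fisher's exact test, Benjamini-Hochberg adjusted), 9 of them measured less often in summer fish. Without the wide-spread arrays it differed for 6 of 26232 probes, all measured less often in summer fish.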
